A study of Mus musculus with 11 samples.

How the data were processed

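RNA was sequenced from 6 lung tumors and 5 adjacent normal lungs of 5 Gprc5a-deficient mice that had received the tobacco carcinogen NNK (nicotine-derived nitrosamine ketone, 50 mg per kg, 3 times a week for 8 weeks). Per the labels, RNA with an integrity number of at least 7 was made into poly-A libraries with the Ion Total RNA-Seq Kit v2 and sequenced on an Ion Proton instrument. Per the submitters' processing notes, STAR 2.4.1d, Bowtie2 2.1.0 and Partek were used with the mouse build mm10 (GRCm38). The role of each tool, the annotation release and the strand setting are not given in the sources used here, so reads of overlapping genes on opposite strands may be counted for either.

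The deposited values are expected counts, with 1 row for each of 36285 RefSeq transcripts and 1 column per library. They are not normalized, and the authors' file writes its largest values to 3 significant digits. Transcripts of the same gene symbol were summed to 24515 genes, and the sums were rounded to whole numbers for the count models. In each library between 78.4% and 86.2% of the gene sums were whole within a tolerance of 0.01 before rounding. Start positions matched RefSeq GRCm38.p6 for 14878 of 23452 compared genes, and the end lay 1 base past the RefSeq end for 14742, so ends are printed with that base removed. A total of 58 symbols lie on more than 1 chromosome. Spreadsheet conversion turned 24 gene names into dates, and 2 of these merge rows from different chromosomes, so none of them is named. Every column was mapped to a library by its name.

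Libraries were grouped by their title tags as normal (5), ADN (3) or ADC (3). The labels do not spell out the tags, and they are used as given. Mouse m335 gave an ADN and an ADC tumor that share its normal lung, mice m368 and m350 gave an ADN tumor, and mice m372 and m378 gave an ADC tumor. The labels give 4 months after NNK for mouse m335, 6 months for mouse m368 and 7 months for the others.

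Genes were kept with filterByExpr of edgeR, which left 15175 genes holding 99.9% of all counts. Libraries were scaled by TMM and fitted with the quasi-likelihood model of edgeR 4.0.16 (robust estimation) in R 4.3.3. The mouse was a fixed block, because the study describes the normal lungs as paired with the tumors. Tumors and normal lungs were compared in a fit of all 11 libraries. ADN against normal, ADC against normal and ADC against ADN came from a fit with 3 groups, and the change of the tumor effect per month from a fit with a linear term. All tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Standard errors (SE) of log2 fold changes were derived from the quasi-likelihood F statistic. Levels are given as CPM on TMM-scaled library sizes unless library totals are named. Levels of sex-linked genes, sums over neighboring tissue lists, and levels of Tcap, Plin4, Satb1, Lipe, Agpat2, Myh7, Nppa, Tnnt2 and the lymphoid tissue genes are on library totals.

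The pairing comes from the mouse identifiers in the labels. As a check, deviations from the group means were correlated between each tumor and its own normal lung, and gave 0.240, 0.109, 0.00493, -0.0444, -0.0367 and 0.254; the own normal lung ranked first for 2 of the 6 tumors. Without the replicate block 2242 genes passed the threshold in tumors against normal lungs, compared with 1759 with it. Sex-linked transcripts were also compared: in mice m335 and m372 the tumors and normal lungs expressed Ddx3y, and in the other mice it was at most 0.412 CPM. Xist was at least 138.5 CPM in those other mice and at most 0.502 CPM in mouse m372. In mouse m335 it was 1.28 CPM in the normal lung, 15.7 CPM in the ADN tumor and 8.77 CPM in the ADC tumor, and the source of these reads was not tested.

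The design, the rule for named genes, the first set of alternatives and 33 gene lists were fixed before the data were examined. The lists were proliferation, alveolar type 2 cell, alveolar type 1 cell, club cell, ciliated cell, neuroendocrine cell, endothelial cell, fibroblast, smooth muscle cell and pericyte, mesothelial cell, cardiac muscle cell, alveolar macrophage, monocyte and other macrophage, neutrophil, T cell, natural killer and cytotoxic cell, B cell and plasma cell, erythrocyte, immune checkpoint, MAPK pathway output, p53 target, NRF2 antioxidant, xenobiotic metabolism, glycolysis and hypoxia, cholesterol and fatty acid synthesis, gastrointestinal and embryonic endoderm, keratin 8 transitional epithelium, epithelial-mesenchymal transition and matrix, NF-kB and STAT3 inflammation, interferon response, MHC class II, MHC class I, and immediate early response. They were tested with camera of limma 3.58.1 on log2 CPM with the mouse block, a preset correlation between genes of 0.01 and a prior count of 2, for lists with at least 5 measured members. The same test with a correlation estimated for each list, and fry, were the alternatives. The P-value of fry tests whether the genes of a list move, on balance, in 1 direction, and does not compare the list with other genes. Lists for skeletal muscle, adipose tissue and thymus were added after the data had been seen.

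Genes are named by a fixed rule. It takes the 10 largest rises and 10 largest falls between tumors and normal lungs among genes past the threshold, with a mean of at least 5 CPM and all 6 tumors on the same side of their own normal lung. It adds up to 3 members of each list that passed its test, the 3 largest rises and falls of the other comparisons (with the condition on all 6 tumors for ADN or ADC against normal lungs), or the 3 smallest unadjusted p-values where none passed, and 13 genes fixed by name. Predicted genes and antigen receptor segments are not named, and some genes that the rule takes are not reported here. Any other gene was chosen after its values were seen, and the text says so.

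The procedure was tested on simulated counts with the real means and library sizes and 15175 genes, of which 100 were changed 2-fold and 100 4-fold. For tumors against normal lungs 13.0% of the 2-fold and 67.0% of the 4-fold changes were recovered, with 9 false calls among 89. For ADC against ADN tumors 0 of the 2-fold and 27.0% of the 4-fold changes were recovered, with 6 false calls among 33.

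Total counts were 19938822 to 46987587 per library. A count of 0 allows up to 3 counts, or 0.0638 to 0.15 CPM depending on the library, and such limits and intervals cover counting error only. Alternatives were fits without the mouse block, with the mouse as a random effect (limma voom), with DESeq2 1.42.0, with RLE, upper quartile or no scaling factors, with no filter or a filter of 20 counts in every library of a group, with transcripts as rows, with the tumors of mouse m335 combined, with prior counts of 0.1 and 1, with other thresholds, and with each mouse or library left out. Scaling by library totals alone, the prior count of 1, lists without each library, and the removal of Rn45s, hemoglobin and neighboring tissue genes were added after the data had been seen. Because the mouse is a block, leaving out either library of a mouse other than m335 takes its pair out of the comparison. Such runs nearly repeat the run without that mouse, and do not tell its libraries apart.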

Results

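Transcripts were counted in 11 mouse lung libraries, from 6 tumors and 5 adjacent normal lungs of 5 mice lacking Gprc5a, a retinoic acid-induced receptor of the lung epithelium. The mice had been given NNK, a nitrosamine of tobacco smoke, and were followed for 4 to 7 months. Tumors carried the tag ADN in 3 libraries and ADC in 3. The comparisons ask how the tumors differ from the normal lung of the same mouse, how the tagged kinds differ, and whether the difference moves with time after NNK. Total counts ranged from 19938822 in the normal lung of mouse m372 to 46987587 in the ADC tumor of the same mouse. Rn45s, a ribosomal RNA precursor, took 7.29% to 19.2% of the counts. Hemoglobin genes took 0.782% to 3.32% in normal lungs and 0.111% to 0.544% in tumors.

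Gprc5a (chromosome 6, 135065662 to 135084708, GRCm38) had 0 to 19 counts in every library, or at most 0.634 CPM on library totals, and fell below the filter for testing. Wild-type lungs were not analysed here.

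Relative to the normal lung of the same mouse, the endothelial, fibroblast, mesothelial and alveolar type 1 lists were lower by camera and the alveolar type 2 and MAPK output lists higher. None held with an estimated correlation (adjusted p from 0.254 to 0.497). By fry the endothelial, fibroblast and mesothelial lists each had an adjusted p of 0.00147. The adjusted p by fry was 0.00764 for alveolar type 1, 0.0383 for MAPK output and 0.112 for alveolar type 2. Other splits drawn of the 11 libraries also called 6 to 25 lists by camera, so camera calls many lists whatever the labels. In the ADC tumor of mouse m335 the alveolar type 2 and MAPK output lists went the other way, each with a median of -0.49. Etv4, a transcription factor induced by MAPK signaling, rose from 0.966 ± 0.66 CPM (SD, n = 5) in normal lungs to 34.6 ± 19 CPM (SD, n = 6) in tumors. Ereg and Areg, ligands of the epidermal growth factor receptor, rose by 5.60 ± 1.02 and 2.51 ± 0.32 on the log2 scale (SE). Cldn5, a tight junction gene of endothelium, changed by -3.03 ± 0.28, and Mfap4, a matrix gene of fibroblasts, by -2.42 ± 0.20. In all, 1759 of 15175 genes passed the threshold in the quasi-likelihood test of edgeR with the mouse as a block, 558 higher and 1201 lower, and 555 of them differed at least 4-fold (104 higher and 451 lower).

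Among the largest rises of genes with a mean of at least 5 CPM, Gja3, a gap junction gene (chromosome 14, 57034460 to 57058030) had 1 count in the 5 normal lungs together and 1633 in the 6 tumors, a ratio of 1219 with an exact 95% interval from 218 to 48158. Without the ADN tumor of mouse m368, which held 744 of these counts, the ratio was 790. Etv4 (chromosome 11, 101769748 to 101785310) changed by 5.09 ± 0.50 with an adjusted p of 0.000823. Adcyap1, a neuropeptide gene, had a mean of 0.0891 CPM in normal lungs and 11.6 ± 16.5 CPM (SD) in tumors. The ADN tumor of mouse m368 stood at 43.8 CPM and the other tumors at 14.0 CPM or less. Ptprn2, a gene of secretory vesicles, went from 2.49 ± 0.8 to 123 ± 70 CPM, a log2 fold change of 5.57 ± 0.84. Dkk2, a Wnt pathway modulator, rose by 4.76 ± 0.62 on the log2 scale, Cldn2, a claudin of leaky epithelia, by 4.23 ± 0.90, and Rhbdl2, a rhomboid protease, by 5.54 ± 1.17. Each was higher than in the own normal lung in 6 of 6 tumors, with an exception. Adcyap1 in the ADC tumor of mouse m378 had 2 counts against 0, too few to tell. The calls of Rhbdl2 and Cldn2 were lost when mouse m350 was left out (adjusted p = 0.0535 and 0.0649) and when mouse m368 was left out (0.0741 and 0.0625).

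Among the largest falls of such genes, Colq (chromosome 14, 31523084 to 31577383), which anchors acetylcholinesterase, had an adjusted p of 0.000318 and a log2 fold change of -4.40 ± 0.30. Tubb1, a tubulin of platelets, changed by -4.52 ± 0.63, Slc7a10, an amino acid transporter, by -4.93 ± 0.88, and Cyp1a1, a carcinogen-metabolizing cytochrome, by -5.03 ± 0.73. Pkhd1l1 changed by -4.19 ± 0.99, and its call was lost without mouse m350, m368 or m372 (adjusted p = 0.0515, 0.063 and 0.077). The others were genes of fat or skeletal muscle: Car3 (-8.61 ± 0.89), Tnnc2 (-6.41 ± 1.10), Atp2a1 (-5.83 ± 0.75), Acta1 (-5.21 ± 0.64) and Tnnt3 (-5.10 ± 0.86). Their levels differed widely between normal lungs, since Atp2a1 reached 116 CPM in the normal lung of mouse m335 and at most 10.7 CPM in the others. Car3 stood at 262 CPM in the normal lung of mouse m368 and at 60.5 CPM or less in the rest. Atp2a1, Tnnt3 and Slc7a10 overlap genes on the opposite strand (Rabep2, Prr33 and Lrp3).

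**Figure D1:**
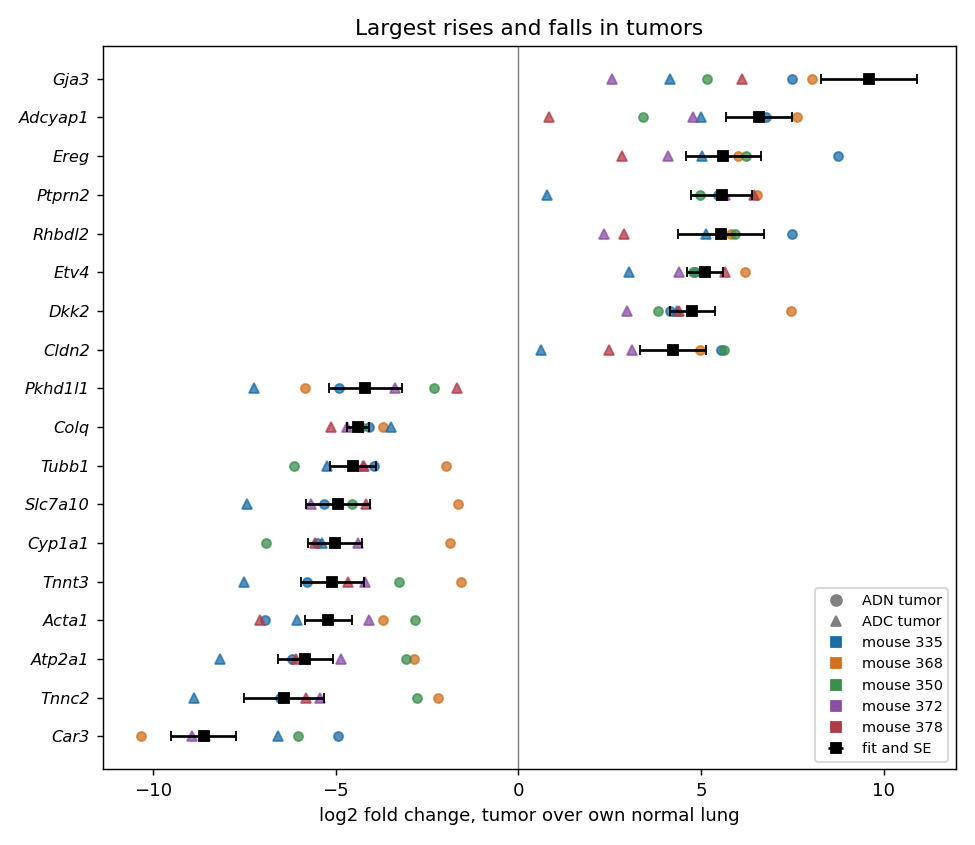
Log2 fold change of each tumor over the normal lung of its mouse (x axis, circles for ADN and triangles for ADC tumors, color by mouse, 0.1 CPM added to both levels) for 8 of the 10 largest rises and the 10 largest falls among genes with a mean of at least 5 CPM, with the fitted value and its SE as a black square and bar. The fitted value of Gja3 depends on the prior count because its normal lungs hold 1 count in all.

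Genes of the normal lung's supporting tissues were lower. Of 24 endothelial genes 19 fell (22 adjusted over the list alone), with a list median of -1.95, among them Calcrl (-2.60 ± 0.22), Vwf (-2.50 ± 0.21) and Cldn5. The list passed camera with an adjusted p of 1.08e-18, but had an adjusted p = 0.254 with an estimated correlation. All 7 measured mesothelial genes fell (7 adjusted over the list alone), such as Upk3b (-3.07 ± 0.46), Upk1b and Gpm6a, with adjusted p = 0.254 with an estimated correlation. In the fibroblast list 12 of 18 fell (13 adjusted over the list alone), including Pdgfra (-1.81 ± 0.18) and Wnt2 (-3.99 ± 0.51), again with adjusted p = 0.254 with an estimated correlation. Of 14 smooth muscle and pericyte genes 6 fell and 0 rose (12 lower and 1 higher adjusted over the list alone), among them Cox4i2 (-1.99 ± 0.20) and Des, with adjusted p = 0.254 with an estimated correlation. All 9 erythrocyte genes fell (9 adjusted over the list alone), with Alas2, the first enzyme of erythroid heme synthesis, at -2.95 ± 0.42, and adjusted p = 0.267 with an estimated correlation. Hbb-b1 and Hbb-bs are listed at nearly the same position, so the split of reads between them is uncertain.

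The epithelial lists moved apart. Of 15 alveolar type 1 genes 7 fell (10 lower and 1 higher adjusted over the list alone), among them Hopx (-1.69 ± 0.22), Spock2 (-2.29 ± 0.29) and Rtkn2 (-1.89 ± 0.25), with adjusted p = 0.267 with an estimated correlation. Of 20 alveolar type 2 genes 5 rose and 0 fell (7 higher adjusted over the list alone), including the surfactant genes Sftpa1 (1.46 ± 0.28) and Sftpd (1.32 ± 0.35) and the chemokine Cxcl15 (1.41 ± 0.30), with adjusted p = 0.497 with an estimated correlation. The calls of Sftpa1, Cxcl15 and Sftpd were lost without mouse m350 (adjusted p = 0.05, 0.0689 and 0.117) and without mouse m378 (0.0524, 0.0674 and 0.0856), those of Cxcl15 and Sftpd without mouse m372 (0.065 and 0.116), and that of Sftpd without mouse m368 (0.076) and under library totals (0.0574). Sftpc changed by 0.78 ± 0.40 (adjusted p = 0.256) and Nkx2-1, the lung lineage factor, by 0.49 ± 0.25 (adjusted p = 0.263). The keratin 8 transitional list, an epithelial state seen after injury, held 7 rising genes of 15 (7 adjusted over the list alone), such as Ereg, Areg and Clu (1.90 ± 0.29), with adjusted p = 0.254 with an estimated correlation. Club cell genes (1 lower of 15, and 3 higher and 5 lower adjusted over the list alone) and ciliated genes (1 lower of 17, and 1 lower adjusted over the list alone) did not pass as lists, with camera adjusted p of 0.497 and 0.524. Scgb1a1, the main club cell secretory gene, had a log2 fold change of -3.10 ± 0.97 and an adjusted p of 0.0754. The neuroendocrine list (1 lower of 5, 3 lower adjusted over the list alone) had a camera adjusted p of 0.055.

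Signaling and stress lists were higher in part. MAPK output genes rose in 4 of 15 (7 adjusted over the list alone), with Dusp4 at 2.28 ± 0.27 and Spred1 at 1.90 ± 0.23, both feedback inhibitors of the pathway, and adjusted p = 0.340 with an estimated correlation. In the p53 target list 3 of 18 rose and 1 fell (3 and 1 adjusted over the list alone), the 3 being Zmat3 (1.41 ± 0.18), Ccng1 (1.17 ± 0.18) and Eda2r (1.62 ± 0.32), with adjusted p = 0.267 with an estimated correlation. The NRF2 antioxidant list had 3 of 15 higher (3 higher and 1 lower adjusted over the list alone), namely Hmox1 (1.08 ± 0.20), Me1 (1.45 ± 0.30) and Aox1 (1.11 ± 0.27), with adjusted p = 0.267 with an estimated correlation. Without the replicate block the NRF2 list had an adjusted p of 0.0586, and its call was also lost without the normal lung of mouse m335 (0.117), the ADC tumor of mouse m335 (0.091) or either library of mouse m378 (0.0753 and 0.0736). The call of Me1 was lost without mouse m350, m372 or m378 (adjusted p = 0.0632, 0.0613 and 0.0655), that of Aox1 without mouse m350, m368, m372 or m378 (0.109, 0.0834, 0.0805 and 0.0875) and under library totals (0.0573), and that of Eda2r without mouse m378 (0.0524). Cdkn2a, a cell cycle inhibitor locus, rose by 1.97 ± 0.45 on the log2 scale (adjusted p = 0.0236, higher in 6 of 6 tumors). The call of Cdkn2a was lost without mouse m350, m368 or m372 (adjusted p = 0.0763, 0.0738 and 0.0676). Trp53 (0.22 ± 0.22), Stat3 (-0.02 ± 0.15) and Egfr (-1.33 ± 0.44, adjusted p = 0.0895) did not pass. The proliferation list passed camera with a median of 0.40 while 0 of its 32 genes passed (0 adjusted over the list alone), and had an adjusted p = 0.8 with an estimated correlation. Its call was lost without the normal lung of mouse m335 (0.568), the ADC tumor of mouse m335 (0.253), the libraries of mouse m378 (0.227 and 0.222) or those of mouse m350 (0.0546 and 0.0561). The list stood at -1.04 in the ADC tumor of mouse m372 and -0.19 in the ADN tumor of mouse m368. The normal lung of mouse m372, which held thymus genes at 518 CPM on library totals, had the highest Tyms, Cdk1 and Tk1 of the normal lungs (13.3, 15.1 and 13.8 CPM). Mki67 stood at 0.33 ± 0.44.

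Metabolic lists differed as well. Of 22 genes of cholesterol and fatty acid synthesis 11 fell and 0 rose (14 lower and 1 higher adjusted over the list alone), among them Idi1 (-1.67 ± 0.18) and Dhcr7 (-1.21 ± 0.16), with adjusted p = 0.270 with an estimated correlation. The xenobiotic metabolism list had 5 lower of 17 (7 lower and 1 higher adjusted over the list alone), with Fmo1 at -3.29 ± 0.26, Cyp4b1 at -3.14 ± 0.30 and Cyp1a1, and adjusted p = 0.364 with an estimated correlation. In the glycolysis and hypoxia list Hk2 (1.92 ± 0.25) and Ldha (1.16 ± 0.19) rose and Vegfa, a vascular growth factor, changed by -1.89 ± 0.28 (2 higher and 1 lower of 18, likewise adjusted over the list alone), with adjusted p = 0.491 with an estimated correlation and a call lost without the ADC tumor of mouse m335 (0.0822). The epithelial-mesenchymal transition and matrix list had 4 lower of 16 (6 adjusted over the list alone), among them the mesenchymal factors Zeb1 (-1.67 ± 0.18) and Zeb2 (-1.30 ± 0.19) and the collagen cross-linking enzyme Lox, with adjusted p = 0.267 with an estimated correlation.

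Immune lists moved by camera with few single genes past the threshold. The ADC tumor of mouse m335 went against the other 5 tumors, with the natural killer, neutrophil, interferon, B cell and T cell lists at medians between 1.08 (natural killer) and 2.56 (T cell) over its own normal lung. Natural killer genes had a median of -2.91 with 1 of 10 called (3 adjusted over the list alone), Prf1 at -3.13 ± 0.54, and adjusted p = 0.370 with an estimated correlation. Neutrophil genes had 1 lower of 10 (1 adjusted over the list alone), S100a9 at -2.65 ± 0.45, with adjusted p = 0.645 with an estimated correlation, 0.0551 without the replicate block and 0.0503 without the normal lung of mouse m368. The T cell list (median -1.56) had 0 called of 17 (0 adjusted over the list alone), with adjusted p = 0.724 with an estimated correlation. The B cell list (-1.50) had 0 of 14 (0 adjusted over the list alone) and the interferon list (-1.02) 0 of 20 (0 adjusted over the list alone), both with adjusted p = 0.726 with an estimated correlation. The T cell call was lost without mouse m372 (0.07), and likewise without only its normal lung or only its ADC tumor (0.0671 and 0.0689). Each of these takes the pair out of the comparison, so the loss does not tell the tumor from the normal lung. That lung also held thymus genes at 518 CPM on library totals, and Tcf7 and Cd8b1 of the T cell list at 305 and 79.4 CPM. The B cell call was lost when any library was left out other than the normal lung and the ADC tumor of mouse m335 (adjusted p from 0.0644 to 0.115), and the interferon call when any library of mouse m350, m372 or m378 was (0.0621 to 0.0669). Under library totals the neutrophil, B cell and interferon calls were lost (0.0638, 0.139 and 0.0919). The MHC class II list went up with a median of 0.65 and 0 of 10 called (0 adjusted over the list alone), with adjusted p = 0.7 with an estimated correlation, and lost its call without the normal lung or the ADC tumor of mouse m335 (0.301 and 0.0741).

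Other lists did not pass camera in tumors against normal lungs. The immediate early list had 5 lower of 17 (6 adjusted over the list alone) and a camera adjusted p of 0.055. The alveolar macrophage list had 1 higher and 1 lower of 16 (1 and 1 adjusted over the list alone, camera adjusted p = 0.312), and the monocyte list 0 of 17 (0 adjusted over the list alone, 0.938). The immune checkpoint list had 1 higher and 1 lower of 14 (1 and 1 adjusted over the list alone, camera adjusted p = 0.730), the higher being Cd276 at 1.54 ± 0.26. The cardiac muscle list had 1 higher of 10 (1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.643). The gastrointestinal list had 1 higher of 13 (1 adjusted over the list alone, camera adjusted p = 0.312), the NF-kB and STAT3 list 0 of 19 (0 adjusted over the list alone, 0.535), and MHC class I 0 of 10 (0 adjusted over the list alone, 0.312). In the gastrointestinal list Gkn2, a gastric secretory gene, had 2 counts in the normal lungs together and 1863 in the tumors, a ratio of 695 with an exact 95% interval from 192 to 5744. The ADN tumor of mouse m368 held 1305 of these counts and the 3 ADC tumors 0, 33 and 13. Without that ADN tumor the ratio was 248. The call of Gkn2 was lost without mouse m368 (adjusted p = 0.0566). Lcn2, an inflammation-induced lipocalin, stood at 0.99 ± 0.31 (adjusted p = 0.0737), Cd274 at -0.05 ± 0.74 and Il6 at -1.88 ± 0.96 (adjusted p = 0.258).

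**Figure D2:**
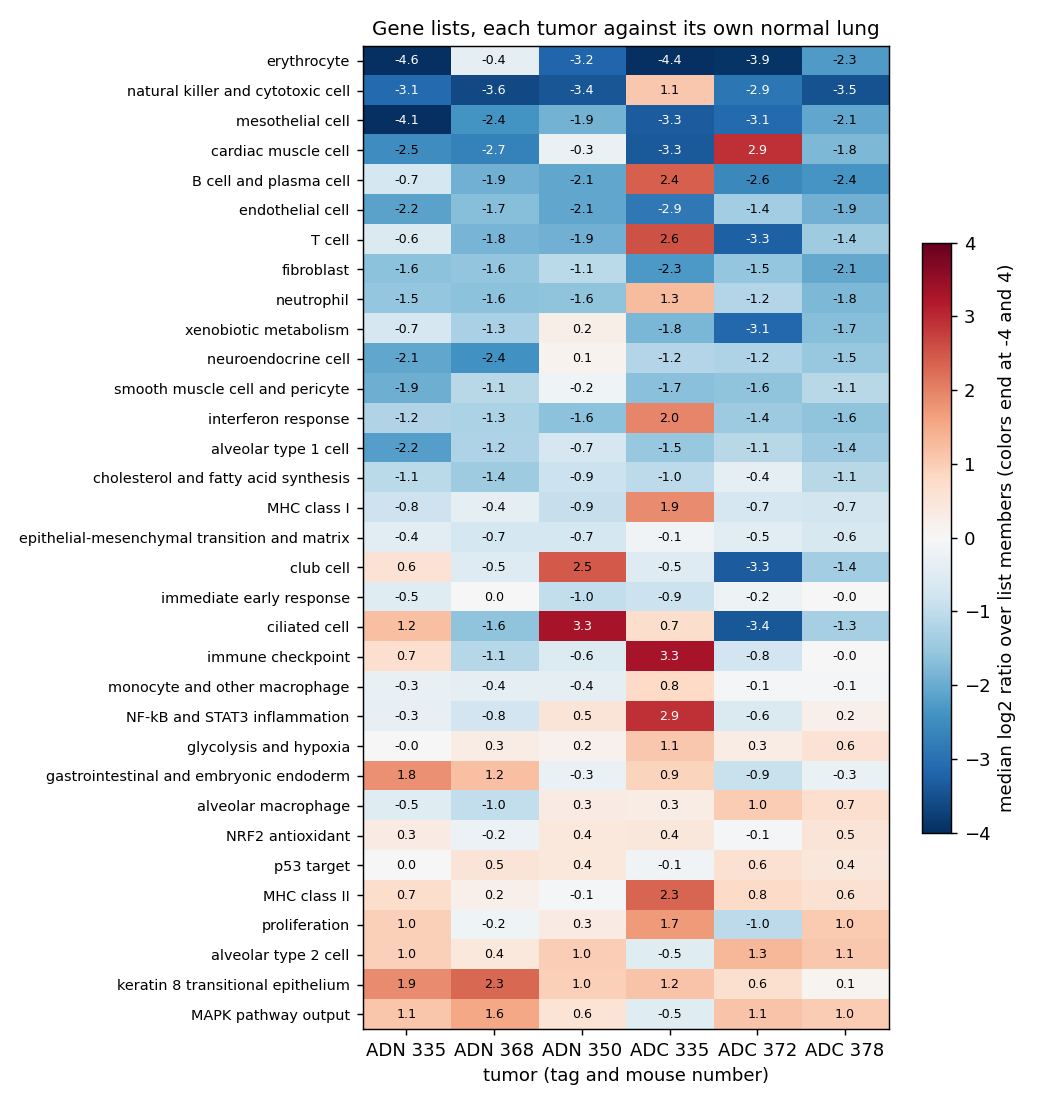
Median log2 ratio of each tumor over the normal lung of its mouse (color and number) for the 33 gene lists (rows) in the 6 tumors (columns, tag and mouse number). The T cell list stands at 2.56 in the ADC tumor of mouse m335 and between -3.28 and -0.57 in the other 5 tumors, while the endothelial list lies between -2.87 and -1.38 in all 6.

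The count of genes in tumors against normal lungs rested on the libraries used. Without the ADC tumor of mouse m335 it was 3377 (1447 higher, 1930 lower), and without the normal lung of that mouse 1032. It also moved by over 1.5 times without mouse m350 (1077), mouse m372 (1082) or mouse m378 (919). Leaving out only the normal lung or only the tumor gave nearly the same counts. These were 1072 and 1103 for mouse m350, 1086 and 1075 for mouse m372, and 917 and 929 for mouse m378. With the mouse as a block either removal takes the pair out, so these counts do not tell the libraries apart. Scaled by library totals alone, 359 genes were higher and 1714 lower, with the median of all genes moving from -0.03 to -0.22.

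In ADN tumors Ereg stood at 122 ± 120.2 CPM (SD, n = 3) against 0.893 ± 0.49 CPM (SD, n = 5) in the normal lungs, a rise of 7.10 ± 0.56 on the log2 scale (SE, adjusted p = 0.00457). Itih2, a hyaluronan-binding protein gene, rose from 0.526 ± 0.70 to 43.1 ± 31 CPM (7.32 ± 0.47, adjusted p = 0.00429), and Gja3 (11.19, adjusted p = 0.00457) completed the 3 largest rises among genes higher in all 6 tumors with a mean of at least 5 CPM. Gkn2, with a fitted rise of 11.01 ± 1.14 (adjusted p = 0.00475) above those of Itih2 and Ereg, was higher in 5 of 6. Its normal lungs hold 2 counts in all, so this fitted value depends on the prior count and its rank is uncertain. Under the same conditions the largest falls were Car3 (-7.72 ± 1.08), Cyp1a1 (-4.80 ± 1.08) and Atp2a1 (-4.77 ± 0.89). In all 1142 genes passed, 407 higher and 735 lower, and 1779 without the replicate block. Scaled by library totals alone, 332 were higher and 1057 lower, with the median of all genes at -0.28. The count fell to 0 in the test of edgeR (2195 at an unadjusted p under 0.05) without the ADN tumor of mouse m335, and was 1972 without the ADC tumor of that mouse. It was 430 and 410 without the normal lung and the tumor of mouse m368, 261 and 264 without those of mouse m350, and 716 and 696 without those of mouse m378.

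In ADC tumors Spag11b, an epididymal defensin-related gene, rose by 4.85 ± 0.79 on the log2 scale (SE, adjusted p = 0.0148), to 15.8 ± 19 CPM (SD, n = 3) from 1.69 ± 2.6 CPM (SD, n = 5). The Spag11b level was 36.7 CPM in the tumor of mouse m378, 10.6 CPM in that of mouse m372 and 0.304 CPM in that of mouse m335. Gja3 rose by 7.62 (adjusted p = 0.00719), a value that depends on the prior count, and Adcyap1 by 5.61 ± 1.03 (adjusted p = 0.0218). Lcn2, fixed by name, rose by 1.39 ± 0.31 (adjusted p = 0.0446). For Adcyap1 the tumor of mouse m378 had 2 counts against 0, too few to tell, and the normal lungs of mice m335 and m372 held 1 count each. Car3 (-9.89 ± 1.19), Tnnc2 (-8.44 ± 1.30) and Atp2a1 (-6.91 ± 0.91) were the largest falls among genes lower in all 6 tumors with a mean of at least 5 CPM. The ADC tumors of mice m335, m372 and m378 held 3, 1 and 1 counts of Car3 and 0, 1 and 2 of Tnnc2. The sizes of these 2 falls are therefore uncertain. Over all 6 tumors Spag11b changed by 3.71 ± 0.83, and that call was lost without the replicate block (adjusted p = 0.23) and without mouse m350, m372 or m378 (0.0663, 0.0758 and 0.105). In all 757 genes passed, 153 higher and 604 lower, and 1546 without the replicate block. Under library totals alone 104 were higher and 818 lower, with the median of all genes at -0.19. The count was 65 and 66 without the normal lung and the tumor of mouse m378, 360 and 361 without those of mouse m372, and 459 without the normal lung of mouse m335.

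ADC and ADN tumors were compared directly, each relative to the normal lung of its mouse. Itih2 stood at 43.1 ± 31 CPM in ADN and 2.39 ± 1.5 CPM in ADC tumors (SD, n = 3 each), Vsig2 at 57.9 ± 27 and 5.12 ± 3.9 CPM, and Lrrc10b at 64.8 ± 30 and 7.26 ± 1.6 CPM, each with an adjusted p of 0.0827 in the test of edgeR. Hnf4a, a regulator of gut and liver genes, stood at 12.7 ± 9.4 CPM in ADN and 0.123 ± 0.14 CPM in ADC tumors (adjusted p = 0.0947). No gene passed in edgeR's quasi-likelihood test, with 0 calls and 992 genes at an unadjusted p under 0.05, while DESeq2 called 129 genes. Without the replicate block edgeR called 3 genes, all lower in ADC, and without the ADC tumor of mouse m335 it called 2.

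By list, 22 of 33 passed camera between ADC and ADN tumors, 13 higher and 9 lower in ADC, and 0 held with an estimated correlation (adjusted p from 0.336 to 0.753 with an estimated correlation, 3 lists at an unadjusted p under 0.05), and fry called 0 (4 lists at an unadjusted p under 0.05). Other splits of the 6 tumors into 3 and 3 called 13 to 21 lists by camera. The higher lists were proliferation, alveolar macrophage, monocyte, neutrophil, T cell, natural killer, B cell, checkpoint, glycolysis, NF-kB and STAT3, interferon, MHC class II and MHC class I. Their medians included 1.92 for interferon genes such as Ifit2, 1.78 for checkpoint genes such as Cd274, and 1.56 for T cell genes. The lower lists were ciliated (-1.45), club (-1.32), xenobiotic (-1.0), gastrointestinal (-0.86), MAPK output (-0.62), keratin 8 (-0.51), fibroblast (-0.50), alveolar type 2 (-0.23) and endothelial (-0.19). With 0 single genes past the threshold over all genes, adjusted over the list alone the alveolar macrophage and monocyte lists each held 3 genes higher, the NF-kB and STAT3 list 1 higher, the keratin 8 list 1 higher and 4 lower, and the gastrointestinal list 2 lower. Without the replicate block the alveolar macrophage, alveolar type 2 and natural killer lists lost their calls (adjusted p = 0.862, 0.266 and 0.0698). Without the ADC tumor of mouse m335 only 12 lists passed, with the T cell list lower in ADC (4.85e-05) and the alveolar type 2 list higher (0.000507). The normal lung of mouse m372 held thymus genes at 518 CPM on library totals. The T cell list stood at -3.28 in the ADC tumor of mouse m372 and -1.44 in that of mouse m378, against -1.93 to -0.57 in ADN tumors. The lower T cell list therefore cannot be told apart from the state of that normal lung. Without the ADC tumor of mouse m335, 12 further lists did not pass: interferon (0.263), B cell (0.104), MHC class I (0.961), MHC class II (0.435), proliferation (0.122), endothelial (0.271), neutrophil (0.819), natural killer (0.764), checkpoint (0.554), MAPK output (0.961), glycolysis (0.147) and NF-kB and STAT3 (0.451). Other libraries left out ended the calls of gastrointestinal (adjusted p from 0.157 to 0.62 without either library of mouse m368 or m372, the ADN tumor of mouse m335 or the ADC tumor of mouse m378), proliferation (0.233 to 0.310 without either library of mouse m368 or m378), keratin 8 (0.0653 and 0.0693 without those of mouse m378), endothelial (0.0646 to 0.0798 without either library of mouse m368 or the ADN tumor of mouse m335) and glycolysis (0.0973 without that tumor). The alveolar type 2 call ended without the normal lung (0.0547) or ADN tumor (0.843) of mouse m335 or either library of mouse m350 (0.112 and 0.0967), and the club call without the ADN tumor of mouse m350 (0.0512).

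The tumor effect was also set against the months after NNK, which rests on 1 mouse at 4 months, 1 at 6 and 3 at 7. Cox6a2, a subunit of muscle cytochrome oxidase, had the smallest p of the genes open to naming, with 1.59 ± 0.25 on the log2 scale per month. Next came Prmt8 (1.22 ± 0.20) and Fabp1, a fatty acid binding protein of liver and gut (1.53 ± 0.29), each with an adjusted p of 0.961. The normal lung of mouse m335, the only mouse at 4 months, had Cox6a2 at 101 CPM against 20.1 to 41.5 CPM in the other normal lungs, and skeletal muscle genes at 828 CPM on library totals. In the test of edgeR 0 genes passed, with 578 at an unadjusted p under 0.05, and DESeq2 called 49. Cox6a2 overlaps Itgad on the opposite strand. Without mouse m335 the term only sets mouse m368, alone at 6 months, against the 3 mice at 7, so it cannot show a trend with time.

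Genes of tissues next to the lung were measured in all libraries, as CPM on library totals, from lists added after the data had been seen. Skeletal muscle genes summed to 828 CPM in the normal lung of mouse m335, 13.6 to 154 CPM in the other normal lungs and 3.39 to 8.51 CPM in the tumors. Adipose genes reached 636 CPM in the normal lung of mouse m368, 27.3 to 167 CPM in the other normal lungs and 2.76 to 8.29 CPM in the tumors. Thymus genes reached 518 CPM in the normal lung of mouse m372 and 43.9 CPM in that of mouse m350. They were at most 1.34 CPM in the remaining normal lungs and 0.412 to 2.87 CPM in the tumors. Of 12 tested skeletal muscle genes 10 were lower in tumors, of 7 adipose tissue genes 2, and of 1 thymus gene 0. With these genes, Rn45s and hemoglobin removed, 1742 genes passed in tumors against normal lungs.

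**Figure D3:**
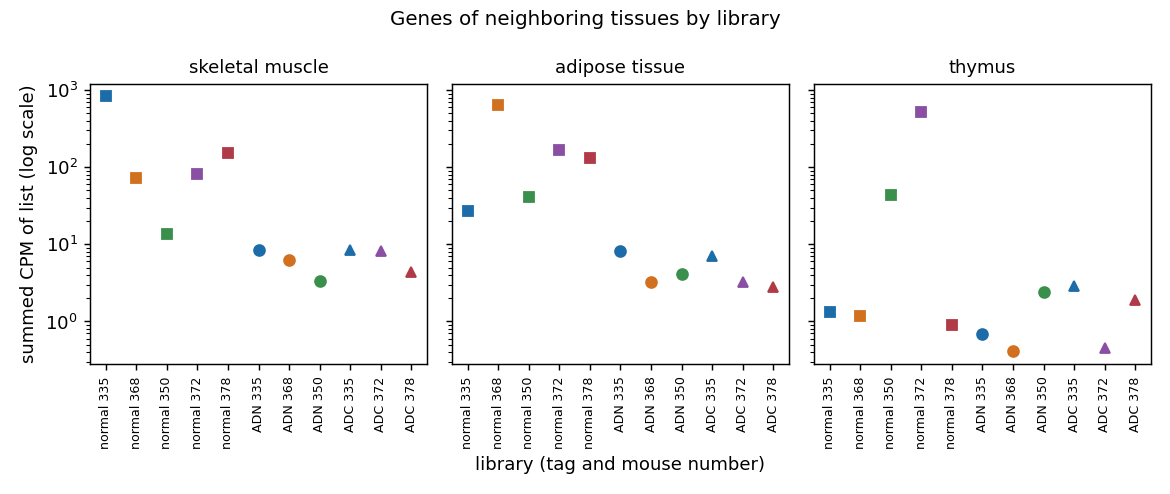
Summed CPM on library totals (y axis, log scale) of the skeletal muscle, adipose tissue and thymus lists in each of the 11 libraries (x axis, squares for normal lungs, circles for ADN and triangles for ADC tumors, color by mouse). Each list peaks in the normal lung of a different mouse, at 828, 636 and 518 CPM.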

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

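The lists of skeletal muscle, adipose tissue and thymus genes, and the comparison of endothelial and fibroblast medians in the ADC tumor of mouse m335, were chosen after their values had been seen; the second lists used to test these patterns were written before theirs had been.

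CPM values of the named genes reported here, and the total count and the shares of Rn45s and hemoglobin, were compared within the 5 normal lungs and within the 6 tumors. Of 314 such groups 97 held a library whose gap to its nearest neighbor, as a share of the range, exceeded Dixon's 95% critical value. That value assumes independent, normally distributed values. CPM of genes that move together need not meet this, so no chance rate is set against the 97. Far above and far below mean such a gap, which can be small in CPM, as for Vsig2 at 22.8 against 17.9 CPM. The ADC tumor of mouse m335 accounted for 35 of them, and the normal lungs of mice m335 and m372 for 13 each. Numbers after a gene name are CPM.

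In the ADC tumor of mouse m335, Cdk1 (25.4), Tcf7 (67.2), Il7r (38.3), Ncr1 (0.811), Eomes (3.65), Fcmr (27.2), Cd79a (215), Usp18 (20.2), Mx2 (1.62), Cd74 (15650.1) and H2-Aa (4811) stood far above the other tumors. The levels of Mcm6 (73.5), Il1r2 (31.2), Foxp3 (43.1), Icos (77.5), Cd2 (82.7), Klrb1c (3.62), Klre1 (1.99), Blk (21.5), Fcer2a (54.2), Cd274 (84.8), Havcr2 (26.8) and Pfkp (82.3) stood far above them as well. The levels of Ctse (7.34), Il1rn (76), Ccl2 (22.6), Bst2 (337), Ifit2 (61.9), Ifit3 (99.3), Ciita (119), H2-D1 (11478), H2-K1 (5479.6) and Tap2 (254) stood far above them as well. In the same tumor, Me1 (95.9) and Aplnr (11.9) stood far below the other tumors. In the ADN tumor of mouse m335, Ereg (260.2), Car3 (0.535), Areg (129), Ccdc39 (4.95), Dusp6 (571) and Epha2 (313) stood far above the other tumors. In the ADN tumor of mouse m368, Adcyap1 (43.8), Dkk2 (94.8), Slc7a10 (4.75), Tubb1 (1.5), Alas2 (27.2), Hbb-b1 (1397), Hbb-bs (761), Hk2 (277), Sftpd (18048) and Gkn2 (45.5) stood far above the other tumors. In the ADN tumor of mouse m350, Calcrl (192), Myh11 (42.1), Lox (21.1), Chad (17.3), Scgb1a1 (9475) and Il6 (1.04) stood far above the other tumors. In the ADC tumor of mouse m378, Spag11b (36.7) and S100a9 (41) stood far above the other tumors. Hemoglobin genes took 0.544% of the counts in the ADN tumor of mouse m368, more than in the other tumors, and the ADC tumor of mouse m372 had the highest total count, 46987587.

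In the normal lung of mouse m335, Etv4 (2.13), Tnnc2 (46.5), Atp2a1 (116), Tnnt3 (36.9), Vsig2 (22.8), Cox6a2 (101), Prmt8 (61.1), Des (193), Vegfa (645), Bpifa1 (39.8) and Epha2 (128) stood far above the other normal lungs. In the same lung, Ccng1 (58.8) stood far below the other normal lungs. In the normal lung of mouse m372, Gja3 (0.0454), Cyp1a1 (159), Itih2 (1.77), Tyms (13.3), Cdk1 (15.1), Tk1 (13.8), Tcf7 (305), Cd8b1 (79.4), Mcm6 (45.1), Gsta3 (149.7), Scgb1a1 (20249) and Mki67 (61.5) stood far above the other normal lungs. In the normal lung of mouse m368, Car3 (262), Spag11b (6.34), Lyz2 (16978), Atp6v0d2 (157), Itgax (179.8) and Gpnmb (255) stood far above the other normal lungs. In the normal lung of mouse m350, Ly6c2 (56.5) and Klre1 (2.6) stood far above the other normal lungs. In the normal lung of mouse m378, S100a9 (269) and Cdkn2a (4.09) stood far above the other normal lungs. Rn45s took 7.29% of the counts in the normal lung of mouse m335, and the normal lung of mouse m372 had the lowest total count, 19938822. The level of Gja3 rests on 1 count.

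Between ADC and ADN tumors 22 gene lists passed camera, and 0 of them with an estimated correlation (3 at an unadjusted p under 0.05). Other splits of the 6 tumors called 13 to 21 lists by camera, so the 22 are not shown to follow the tags.

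Skeletal muscle, adipose and thymus genes each peaked in the normal lung of a different mouse. All tested genes had a median log2 ratio of -0.00551 between the normal lung of mouse m335 and the others, against 3.21 for the muscle list. These levels were TMM-scaled, which brings the median of all genes near 0 by construction. That median therefore does not test for a scaling error. The TMM factor was 1.05 for that lung and 1.06 to 1.11 for the other normal lungs, so library totals scaled it nearly as they did the others. Pieces of neighboring tissue may have been taken with these lungs: in second lists, 10 of 11 muscle genes peaked in the normal lung of mouse m335 (exact binomial p = 9.22e-07), 7 of 9 adipose genes in that of mouse m368 (0.000314) and 7 of 7 thymus genes in that of mouse m372 (1.28e-05). The most abundant of those that peaked were Tcap (26.5 CPM), Plin4 (30.3 CPM) and Satb1 (139.5 CPM), while Lipe and Agpat2, which did not, had medians of 52.9 and 74.5 CPM in the other lungs. The binomial p treats genes as independent, but genes of 1 tissue move together and each peak rests on 1 library. Such a p does not measure replication, and a second list of the same tissue cannot decide the cause. No biological explanation was tested.

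Immune genes stood high in the ADC tumor of mouse m335, with a T cell list median of 2.56 over its own normal lung. A lower share of tumor cells that raised all other cell types alike is argued against, because the endothelial list stood at -2.87 and the fibroblast list at -2.28 in this tumor, while the endothelial list lay between -2.16 and -1.38 in the other tumors. Lymphoid tissue in or beside this tumor may have contributed: 9 of 11 lymphoid tissue genes peaked in it (exact binomial p = 3.94e-06), among them Ltb at 291 CPM, Cxcl13 at 136 CPM and Cd37 at 127 CPM. The binomial p treats genes that move together in 1 library as independent, so it does not measure replication. An immune infiltrate that belongs to the tumor would raise the same genes, so the test leaves both open. The ADC tag and the 4 months after NNK were not tested as causes.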

How the results depend on the processing

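Scaling by library totals, leaving out single libraries for the gene lists, the prior count of 1 and leaving out Rn45s, hemoglobin and neighboring tissue genes were chosen after the data had been seen; the other alternatives were planned. For tumors against normal lungs (1759 genes), DESeq2 called 3286 and an adjusted p under 0.01 left 779; without the replicate block (2242), with a random mouse effect (2329), other scalings (1775 and 1790), other filters (1602 and 1813), transcripts (1350), library totals (2073) or the tumors of mouse m335 combined (2363) the count stayed within 1.5 times. Leaving out a mouse or a library gave 917 to 3377. For ADN tumors against normal lungs (1142), the count was 1779 without the replicate block, 1757 with a random mouse effect, 2931 with DESeq2 and 507 with transcripts, and 0 to 1972 with a mouse or library left out. For ADC tumors against normal lungs (757), these were 1546, 1435, 1858 and 317, and 65 to 1067. For ADC against ADN tumors (0), edgeR without the replicate block called 3, limma with a random mouse effect 2, DESeq2 129, no filter 5 and the stricter filter 1, with 0 to 2 when a mouse or library was left out. For the months term (0), DESeq2 called 49, and leaving out a mouse or library gave 0 to 405, the highest without mouse m335. With an estimated correlation 0 of the 22 lists held in tumors against normal lungs (5 at an unadjusted p under 0.05) and 0 of the 22 between ADC and ADN tumors; fry called 15 (13 of them shared with camera) and 0. Without the replicate block 20 and 22 lists passed, and leaving out a mouse or library gave 19 to 24 and 12 to 22. The cause was not tested for these changes, except that transcripts and stricter thresholds divide or remove calls by construction. Left-out libraries leave fewer samples, but some counts rose, as to 3377 for tumors against normal lungs without the ADC tumor of mouse m335. Leaving out a library can leave 2 tumors of a kind, and the fit pools the spread over all groups. For tumors against normal lungs, alternatives were run on the 159 tested named genes. No gene that passed in the main fit or in the alternative changed sign. Sign changes of genes that passed in neither were not counted. All kept their side of the threshold under RLE factors and other prior counts. Without the replicate block 147 kept it, 11 passed in addition, and Spag11b lost its call (adjusted p = 0.23; the range over its lost calls was 0.0663 to 0.23). Under library totals 153 kept it, 3 passed in addition and 3 lost their calls (Lamp3, Aox1 and Sftpd). Without mouse m335 29 further genes passed and Myh11 lost its call, and without the other mice 7 to 11 calls were lost. The pseudocount alternatives apply to normalized values only and were not run. Small changes of rare genes lie beyond this depth, since 0 counts allow up to 0.0638 to 0.15 CPM.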

Other observations

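The tests of Myh7 were chosen after its values had been seen; the counts of other splits were planned, except those within mice for ADN and ADC tumors and for the lists, which were added after the data had been seen.

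Ratios of airway and muscle genes to the own normal lung varied between single tumors. In the ADN tumor of mouse m350 the ciliated list stood at a median of 3.28 and the club list at 2.45 over the own normal lung, and in the ADC tumor of mouse m372 at -3.40 and -3.32. The normal lung of mouse m372 had the highest Scgb1a1 of the normal lungs (20249 CPM, the next 6285 CPM), so its ratios may reflect that lung as well as the tumor. Cardiac muscle genes had a median of 2.91 in the ADC tumor of mouse m372 and between -3.35 and -0.27 in the other tumors. Nppa, the atrial natriuretic peptide gene, reached 287 CPM there and at most 0.567 CPM in the other tumors, and Tnnt2, cardiac troponin T, 37.5 CPM. In the normal lung of mouse m372 Nppa stood at 18.1 CPM. Genes and libraries here were picked after their values had been seen.

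Lymphoid genes likewise varied between tumors. Ccl19 and Cxcl13, chemokines of lymphoid tissue, stood at 42.8 and 136 CPM in the ADC tumor of mouse m335, with medians of 0.696 and 1.13 CPM over the other tumors. Ccl21a was 24.7 CPM in that tumor and 22.9 CPM in the median of the others.

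Myh7, a slow and cardiac muscle myosin gene, was chosen after its values had been seen. It rose in tumors by 4.32 ± 0.98 on the log2 scale (SE, adjusted p = 0.0231 by edgeR, higher in 5 of 6 tumors, the exception being the ADC tumor of mouse m335 at 40.2 CPM against 112 CPM on library totals), and its paralog Myh6 by 3.68 ± 0.54 (adjusted p = 0.00341, 6 of 6). Muscle in the tumor pieces is argued against as the whole source, since 8 slow and cardiac muscle genes summed to 0.0226 of the Myh7 level in the median tumor (range 0.00171 to 0.0822). Reads of Myh6 are argued against too, since Myh6 was at most 0.197 of Myh7 in any tumor. The reverse, reads of Myh7 counted as Myh6, was not tested. On library totals Myh6 stood at 5.42 to 10.5 CPM in the ADN tumors, where Myh7 stood at 739 to 2225 CPM. The highest Myh6 level, 237 CPM, was in the ADC tumor of mouse m372. Expression of Myh7 by tumor cells may account for the rise, as a hypothesis, and no test here tells which cells hold the transcript.

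Other splits of the libraries were fitted the same way. Each number of splits given here includes the real split, so 1 means that no other split gave as many. For tumors against normal lungs, 1 of 100 splits drawn gave as many genes as the real one (1759, highest other 8), but most of these exchange libraries across mice. Among 48 splits within mice 1 did, a share under 0.05. The highest other, 1732, set the ADC tumor of mouse m335 with the 5 normal lungs against the other tumors. That tumor stands apart from the rest, which is a structure of the samples. For ADN against normal 1 of 56 splits gave as many (1142, highest other 12), and for ADC against normal 1 of 56 (757, highest other 0), but most of these exchange libraries across mice. Only 8 splits of each part all 3 pairs, too few for a share under 0.05: 1 of 8 gave as many for ADN (highest other 12) and 1 of 8 for ADC (highest other 0). For ADC against ADN tumors there are only 10 splits, too few for a share under 0.05: all 10 gave at least the real count of 0 genes (highest other 0), and 1 gave as many as 22 lists (highest other 21). For the lists in tumors against normal lungs 8 of 100 splits gave at least 22 (highest other 25), and within mice 2 of 48 did (highest other 22), a share under 0.05, so whether chance is excluded for the number of lists depends on which splits are compared.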
